A study of Homo sapiens with 8 samples.

How the data were processed

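Total RNA of HepaRG cells was labelled with biotin and read on 8 Illumina arrays, 4 of cells given DMSO (0.01%) and 4 of cells given TCDD (10 nM), each for 24 h, per the labels' protocols. The signal of each probe on each array was deposited as an intensity on a linear scale, with no background subtracted and no normalization between arrays. Each signal came with a detection p-value per the file headers, and the values moved in steps of 1 in 770. How the detection p-value was computed, the scanner and its software are not given in the sources used here. The authors also deposited a table of normalized values, in intensity units on a linear scale. That table held 47314 of the 47323 probes (9 were missing), and 100% of its values lay within 1% of a quantile normalization of the signals computed here.

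The gene symbols came from the series' probe table. Of 47323 probes, 30110 carried 1 symbol, 8 carried several and 17205 had no gene listed. A RefSeq table of human genes matched 30071 probes, and 0 symbols were changed by it. Genomic positions of the probes were not used here.

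Signals were background corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, with the background inferred from the detection p-values and an offset of 16. Probes with a detection p-value under 0.05 on at least 4 of the 8 arrays were kept. This left 21790 probes, 5313 of them without a symbol, and 12189 genes. Each gene was represented by its kept probe of highest mean level, and 3401 genes had over 1 kept probe. A linear model with group as the only term was fitted to every kept probe with limma's lmFit, and eBayes with a trend gave p-values. These were adjusted by the Benjamini-Hochberg method over the kept probes. A gene was called when its probe had an adjusted p under 0.05. Errors of log2 fold changes are standard errors from this model, all tests were two-sided unless stated, and the 8 arrays set the precision. A fold against a group with no array above background was computed as a lower bound.

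Replicate numbers 1 to 4 were shared by both groups. The labels do not say what a number stands for, so the pairing rests on the data. The deviations of the arrays from their group means, over all kept probes, correlated at 0.352, 0.524, 0.553 and 0.572 between the DMSO and TCDD arrays of numbers 1 to 4. Between arrays of different numbers the correlation lay between -0.547 and 0.295, and 8 of 8 arrays correlated best with their own number. All same-number correlations were over 0.1, the limit set beforehand, so the fit with replicate number as a block is reported as the paired fit.

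The 28 gene lists (516 genes, of which 475 had a named probe and 375 were tested) were written before the data were examined, together with the tests, the filter and the main alternatives. They covered AhR target genes, the AhR complex and coactivators, NRF2 target genes, other cytochrome P450 enzymes, conjugating enzymes, hepatic transporters, hepatocyte secreted proteins and hepatocyte transcription factors. Markers covered biliary and liver progenitor cells, mesenchymal and stellate cells, and endothelial and blood cells. Further lists held acute-phase proteins, cytokines and chemokines, proliferation genes, p53 target genes, endoplasmic reticulum stress genes, cholesterol synthesis genes, fatty acid and triglyceride genes, glucose metabolism genes, bile acid genes and coagulation and complement genes. The last were interferon-stimulated genes, TGF-beta and YAP target genes, hypoxia-inducible genes, circadian clock genes, matrix metalloproteinases and inhibitors, immediate early genes and ribosomal protein genes. Of the tested genes, NQO1, CYP51A1, SLC10A1 and SLC2A1 each stood on 2 lists, as did NR1H4, NR0B2 and ABCB11, which were not tested. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, which compares the members with all other genes, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks whether the members move one way on balance, were run beside it.

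Genes named in the text were the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, 9 genes fixed beforehand (CYP1A1, CYP1A2, CYP1B1, AHRR, TIPARP, NQO1, ALDH3A1, AHR and ARNT), and up to 4 called members per list with the smallest adjusted p. Where a list had no called member, the member of smallest p could be named. Up to 4 members per list with the smallest adjusted p in the paired fit were added by a rule chosen after seeing the data, and HSP90AA1, FTL, CP, SERPIND1, IL18 and DUSP1 were named to complete small counts after their values were seen.

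The alternatives were no background correction, median scaling, the authors' normalized values, no filter and a stricter filter (detection p under 0.01 on all 4 arrays of a group), eBayes without a trend and robust, array weights, the mean of a gene's probes, a 1.5-fold threshold, the replicate block, and each array left out in turn. The same settings with the block kept, and each replicate number left out in the paired fit, were chosen after seeing the data. All 35 splits of the 8 arrays into 4 and 4 were fitted in the same way. The calling was tested on simulated data for 21790 probes, of which 67 were changed by 0.5 (log2), 67 by 1 and 66 by 2. Without the block it recovered 4.48%, 64.2% and 95.5% of these, with 0 false calls. With the block it recovered 22.4%, 83.6% and 98.5%, and 7 calls (4.90%) were false. The simulated data were built from the fitted effects of replicate number and independent noise, so the block held in them by construction. The gain with the block therefore does not show that the block suits the real data. The simulated lists were tested without the block, and the noise added to each gene was independent of that of other genes. With no list shifted, camera called 0 of 28 simulated lists. This does not show how often correlated noise makes camera call a list, and the estimated correlation reached 0.629 in the real data (acute-phase proteins). With 1 list raised by 0.5 (log2) camera called that list (adjusted p = 3.22e-12), while camera with an estimated correlation and fry called 0 lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.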

Results

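Gene expression was measured on Illumina arrays in HepaRG cells, a human liver tumour line whose progenitor-like cells can become hepatocyte-like or biliary-like. The labels describe the cells as hepatic progenitors. Total RNA came from cells given the solvent DMSO (0.01%) or TCDD (10 nM) for 24 h, with 4 arrays per group. TCDD is a dioxin and a persistent pollutant that binds the aryl hydrocarbon receptor (AhR), a transcription factor activated by its ligands. The median probe signal lay between 123 and 187 intensity units in the DMSO arrays and between 125 and 167 in the TCDD arrays. Of 47323 probes, 20274 (DMSO array 4) to 22265 (TCDD array 1) were above background at a detection p under 0.05. DMSO array 4 stood apart with the highest median signal, 187 against 123 to 133 in the other DMSO arrays. The number of arrays limits the precision, and the p-values measure only the spread between these samples, which may be technical. Arrays that shared a replicate number resembled each other across the groups, so values with replicate number as a block (the paired fit) stand beside those of the fit without it.

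The comparison asks which genes changed their mRNA level after a day of TCDD. The 2 largest rises among genes with a symbol were those of CYP1A1 and CYP1B1, genes that AhR is known to switch on. CYP1A1, an enzyme that oxidises polycyclic aromatic compounds, rose by 7.0 ± 0.13 on the log2 scale (SE, n = 4 per group, 128-fold, adjusted p = 1.37e-10). Its level was 5.12 ± 0.13 (SD) in DMSO, where 1 of 4 arrays was above background, and 12.12 ± 0.21 in TCDD. The size of the CYP1A1 rise therefore leans on the background correction, and it was 4.85 without one. CYP1B1, a related enzyme, rose 13.2-fold (log2 3.72 ± 0.24, adjusted p = 2.35e-05). TIPARP, an ADP-ribosyltransferase that restrains AhR, rose 6.11-fold (log2 2.61 ± 0.14, adjusted p = 9.59e-06).

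In all, 294 of 12189 genes were called at an adjusted p under 0.05, which is 2.41% of those tested. Of these, 135 were higher and 159 lower in TCDD, and 99 changed at least 2-fold (62 higher and 37 lower). With the paired fit 2577 genes were called (1165 higher and 1412 lower), which is 21.1% of those tested, and 147 changed at least 2-fold. Paired calls in a list at or below that share do not set the list apart from other genes. All 294 genes were among the 2577, and 2478 of the 2577 moved one way in 4 of 4 pairs. The groups did not overlap in 1270 genes (10.4%), against 2.86% by chance, and in 293 of the 294 called genes. Without 1 array the count fell to 151 (DMSO array 1), 143 (DMSO array 2), 158 (DMSO array 3), 122 (TCDD array 1), 132 (TCDD array 3) or 190 (TCDD array 4), and it was 478 without DMSO array 4. The paired count was 1286 without replicate number 3 and 2158 without number 4, which holds DMSO array 4. Median scaling in place of quantile normalization moved the median of all genes up by 0.25 (log2) in TCDD, and all changes given here are relative to the median gene as quantile normalization sets it. Under median scaling 489 genes were called, 89.2% of them higher, against 45.9% of the 294. With the paired fit and median scaling 1477 genes were called, 88.3% of them higher. CYP1A1 had an adjusted p of 6.49e-280 in that fit, against 1.83e-17 with quantile normalization. So few arrays cannot give either value from a gene's own spread. The p-values of the paired fit therefore rest in part on spread shared between genes, and its 2577 calls became 1413 with robust eBayes without a trend. Under median scaling they rest on that shared spread still more. The shift of the median gene, 0.71 in pair 4 and 0.04 to 0.17 in the others, adds to that spread. A call lost under median scaling in the paired fit therefore does not show that a gene did not change.

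**Figure D1:**
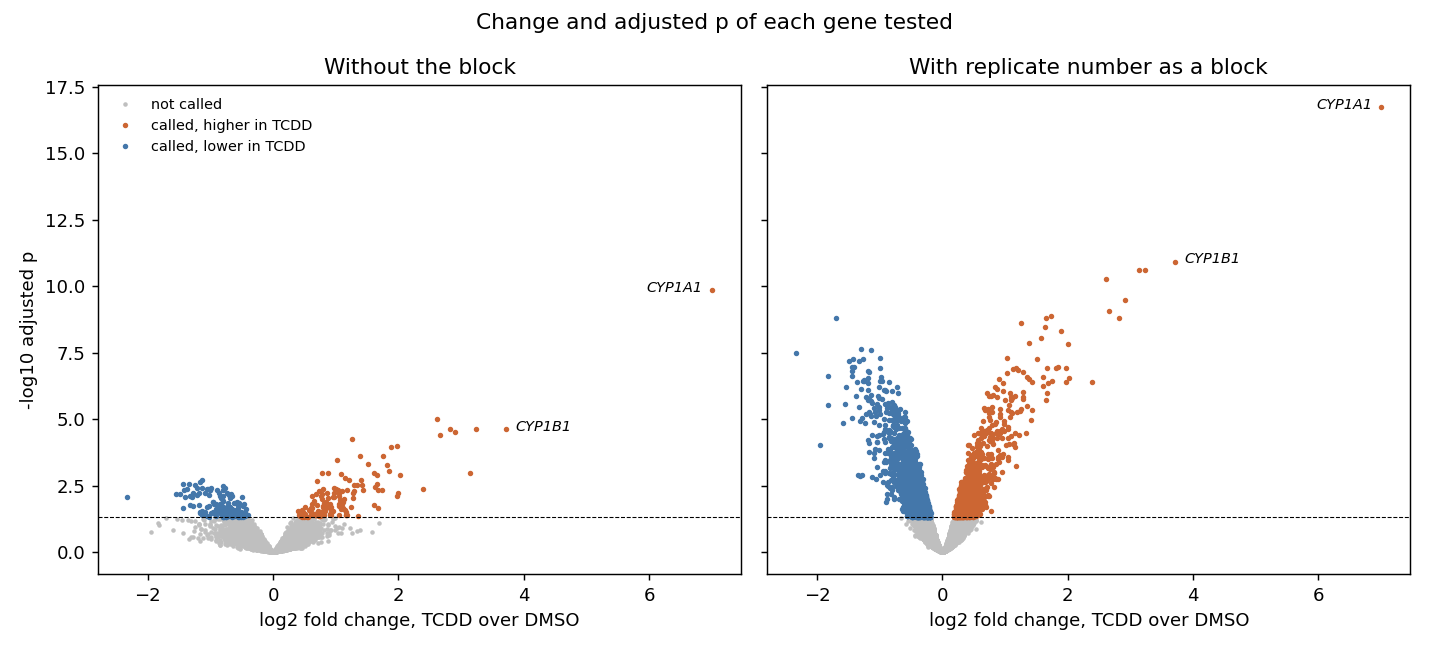
Log2 fold change (x axis, TCDD over DMSO) against the adjusted p on a negative log10 scale (y axis) for each of the 12189 genes tested, without (left) and with (right) replicate number as a block. The dashed line marks an adjusted p of 0.05, which 294 genes passed on the left and 2577 on the right.

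Also among the 12 largest rises, SLC7A5, a carrier of large neutral amino acids, rose 7.08-fold (log2 2.82 ± 0.18, adjusted p = 2.35e-05), and SLC7A11, the cystine carrier that feeds glutathione synthesis, rose 3.95-fold (log2 1.98 ± 0.16, adjusted p = 1.03e-04). SLC14A1, a urea transporter, rose by 2.39 ± 0.33 (adjusted p = 0.00439), with 3 of 4 DMSO arrays above background. SLCO2A1, a prostaglandin transporter, rose by 2.0 ± 0.29 (adjusted p = 0.00584). NKD2, which restrains Wnt signalling, rose 9.44-fold (log2 3.24 ± 0.21, adjusted p = 2.35e-05). SCG5, a chaperone of secretory granules, rose 8.80-fold (log2 3.14 ± 0.34, adjusted p = 0.00106). CCL20, a chemokine, rose 7.51-fold (log2 2.91 ± 0.20, adjusted p = 3.18e-05), and IL17RB, an interleukin receptor chain, rose 6.31-fold (log2 2.66 ± 0.19, adjusted p = 3.82e-05). SHISA2 was above background on 0 of 4 DMSO arrays and 4 of 4 TCDD arrays and was at least 3.06-fold higher (adjusted p = 0.00124).

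The largest fall was that of CYP4B1, a cytochrome P450 enzyme. It fell by 2.33 on the log2 scale (SE 0.37, 5.02-fold lower, adjusted p = 0.00818), and a second CYP4B1 probe gave -1.88. SOX9, a transcription factor of biliary and progenitor cells, fell by 1.37 (SE 0.19, adjusted p = 0.00423). RSPO1, a secreted activator of Wnt signalling, fell by 1.55 (SE 0.23, adjusted p = 0.00652), with 1 of 4 TCDD arrays above background. CGN, a tight junction protein, fell by 1.44 (SE 0.18, adjusted p = 0.00269), and PPL, a protein of desmosomes, fell by 1.29 (SE 0.21, adjusted p = 0.00868). PRODH, the first enzyme of proline breakdown, fell by 1.33 (SE 0.17, adjusted p = 0.00269). ADGRF5, NUAK2, NSG1 and STAC2 fell by 1.48, 1.42, 1.40 and 1.33. CISH, an inhibitor of cytokine signalling, fell by 1.44 (SE 0.27, adjusted p = 0.0215), but its adjusted p was 0.0677 without DMSO array 1, 0.0663 without DMSO array 2 or 3, 0.0686 without TCDD array 1 and 0.0760 without TCDD array 3. DLX5, a homeobox gene, fell by 1.32 (SE 0.23, adjusted p = 0.0169), and its adjusted p was 0.0536 without DMSO array 2, 0.0555 without DMSO array 3, 0.0669 without TCDD array 1 and 0.0512 without TCDD array 3. All 12 of these falls were called with the paired fit, CISH at an adjusted p of 1.56e-07 and DLX5 at 1.14e-05.

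**Figure D2:**
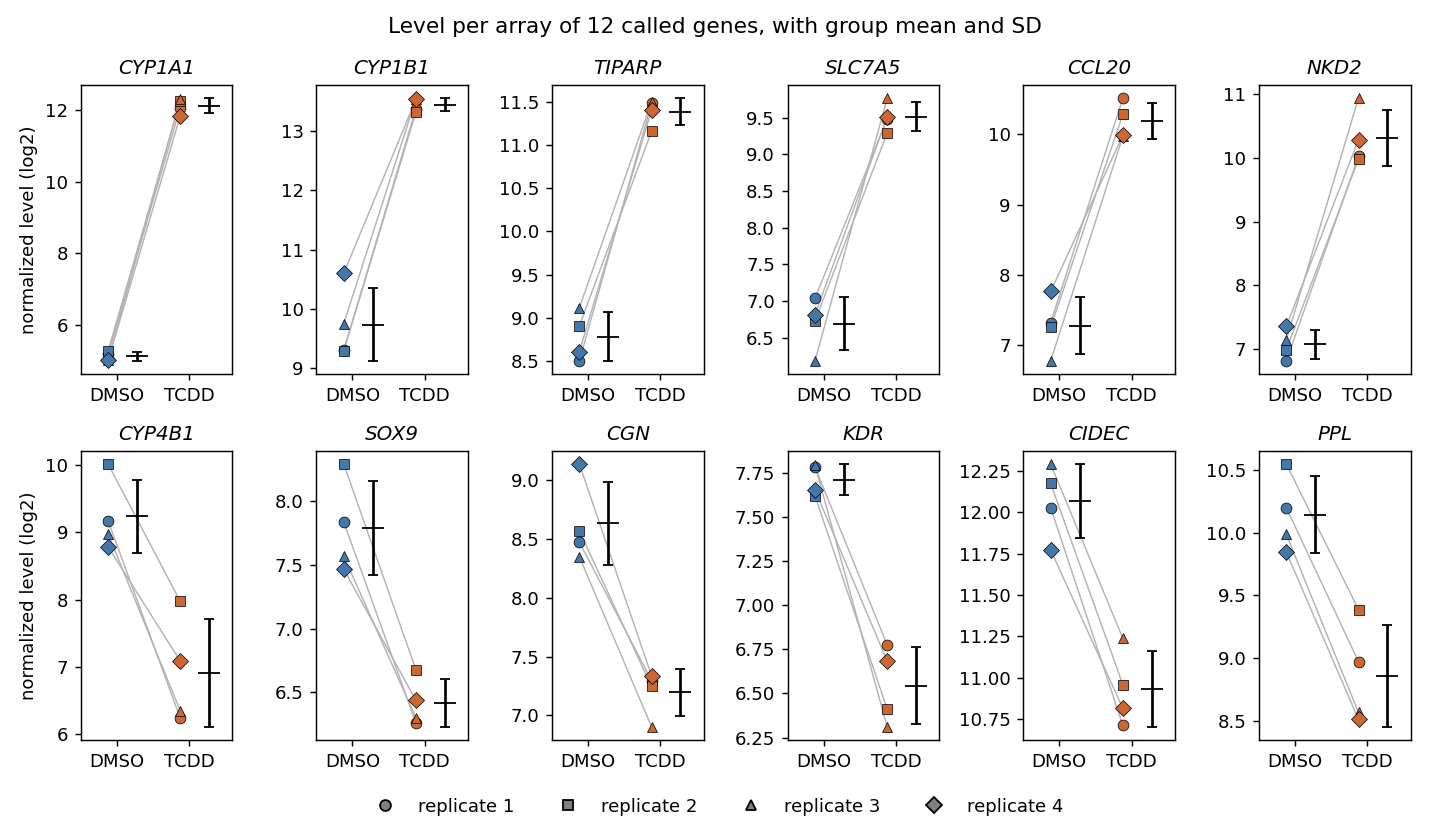
Normalized level (log2, y axis) on each array for 6 genes that rose (top) and 6 that fell (bottom), with lines joining arrays of the same replicate number and bars showing the mean and SD of 4 arrays. The CYP1A1 levels lie between 5.00 and 5.26 in DMSO and between 11.84 and 12.31 in TCDD.

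Of the 14 AhR target genes measured, 10 rose, 0 fell and 4 did not pass the test. Adjusted over the list alone, 12 rose, and with the paired fit 12 rose. Beside CYP1A1, CYP1B1, TIPARP and SLC7A5, ALDH3A1, an aldehyde dehydrogenase, rose by 1.03 ± 0.10 (adjusted p = 3.43e-04). The list as a whole was higher than other genes (median log2 change 1.39, camera adjusted p = 4.46e-19, and adjusted p = 0.0289 with an estimated correlation). In the paired fit these were adjusted p = 1.04e-18 and adjusted p = 0.0634 with an estimated correlation. The 4 members without a call were NQO1, a quinone reductase (0.44 ± 0.14, adjusted p = 0.150, and 0.00138 with the paired fit), UGT1A6 (0.43, adjusted p = 0.239), CYP2S1 (0.03) and AHRR, the AhR repressor gene (-0.21 ± 0.21, adjusted p = 0.669, and 0.01 with median scaling). UGT1A6 and CYP2S1 were chosen after their values were seen. UGT1A1 passed as a member of the list, but probes of the UGT1A genes share exons, and the other 7 UGT1A probes gave -0.11 to 0.70 without a call. CYP1A2, a related P450 enzyme, was above background on 0 of 4 DMSO and 1 of 4 TCDD arrays, so it did not pass the filter. Without the filter CYP1A2 was higher in TCDD (adjusted p = 0.0175, paired 0.00238), with no size given because its DMSO signal was background, and 11 of 16 members rose (13 with the paired fit).

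Of 10 genes of the AhR complex and its coactivators, 0 rose and 1 fell (2 rose and 2 fell adjusted over the list alone; 3 rose and 2 fell with the paired fit, and 1 and 0 with median scaling in that fit). The list did not differ from other genes (camera adjusted p = 0.993, paired 0.807). AHR itself fell by 0.45 (SE 0.090, adjusted p = 0.0307), while its other probe gave 0.06. The AHR call was lost without DMSO array 2 (adjusted p = 0.0928), DMSO array 3 (0.0633), TCDD array 1 (0.0624), TCDD array 2 (0.0527), TCDD array 3 (0.10) or TCDD array 4 (0.0801). Under median scaling AHR gave -0.13 (adjusted p = 0.717), and without the block its adjusted p ran from 0.0277 to 0.717 over the settings. With the paired fit it was 4.06e-04, and 0.755 under median scaling. ARNT, the partner of AHR, gave -0.14 ± 0.22 (adjusted p = 0.781). Chaperone genes of the complex, HSP90AA1, HSP90AB1 and PTGES3, rose by 0.26, 0.37 and 0.41 with the paired fit, and the coactivator NCOA1 fell by 0.60. The 2 other NCOA1 probes gave -0.21 and -0.02, and under median scaling NCOA1 gave -0.30 (paired adjusted p = 0.344).

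Of 16 targets of NRF2, a regulator of antioxidant defence, 4 rose and 0 fell (8 rose and 1 fell adjusted over the list alone, and the same numbers with the paired fit). In the paired fit 5 rose without replicate number 3, and 7 rose and 0 fell under median scaling. SLC7A11 had the largest rise. SRXN1, GCLC and GCLM, which serve peroxide repair and glutathione synthesis, rose by 0.59 ± 0.12 (adjusted p = 0.0291), 0.61 ± 0.13 (adjusted p = 0.0404) and 0.50 ± 0.093 (adjusted p = 0.0201). GCLM was lost without DMSO array 2 (adjusted p = 0.0658), TCDD array 1 (0.0807) or TCDD array 3 (0.0760). SRXN1 was lost without DMSO array 2 (0.0732), DMSO array 3 (0.0857), TCDD array 1 (0.0843), TCDD array 3 (0.0993) or TCDD array 4 (0.0648). GCLC was lost without DMSO array 1 (0.103), 2 (0.0816) or 3 (0.0917), and without TCDD array 1 (0.103), 3 (0.117) or 4 (0.101). All of these were called with the paired fit, in which FTL, the ferritin light chain gene, fell by 0.30. The NRF2 list was higher than other genes (median 0.23, camera adjusted p = 4.55e-05, paired 7.12e-05), with adjusted p = 0.196 with an estimated correlation and adjusted p = 0.214 with an estimated correlation in the paired fit.

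**Figure D3:**
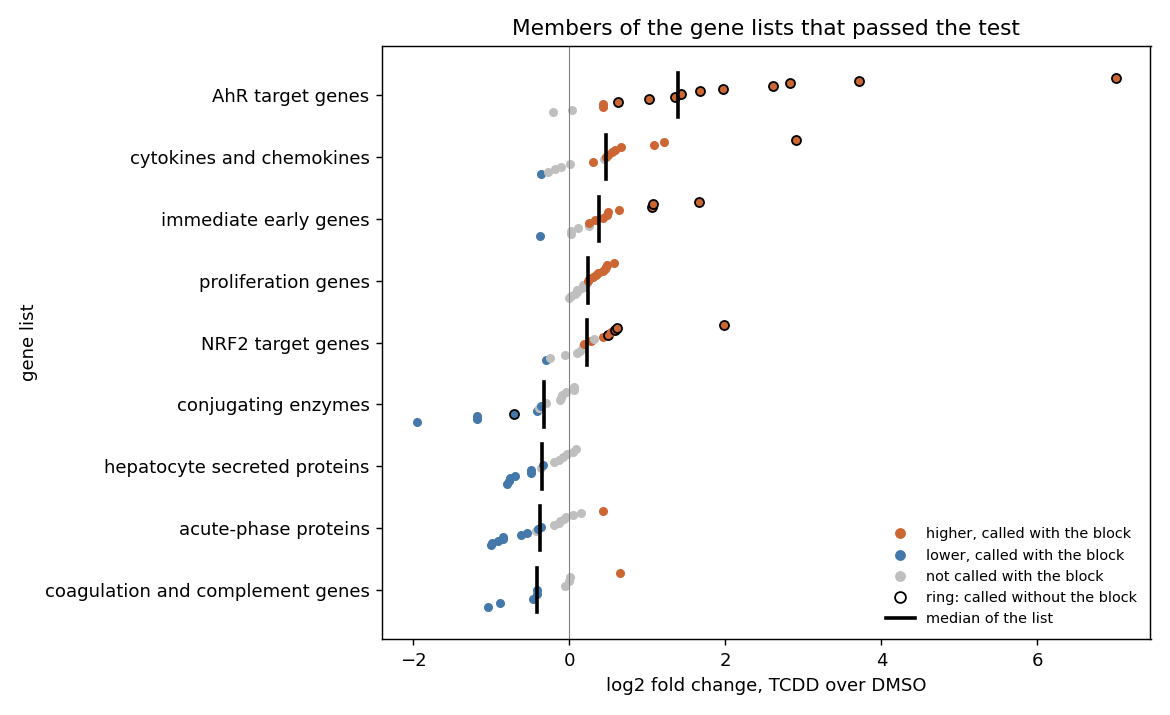
Log2 fold change (x axis, TCDD over DMSO) of each measured member of the 9 gene lists (y axis) that passed the camera test, 7 without the block and 9 with it. Colours mark members called with replicate number as a block, rings mark those called without it, and bars mark the medians, from -0.41 for coagulation and complement genes to 1.39 for AhR target genes.

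4 lists of hepatocyte genes were lower than other genes in TCDD with the paired fit, the conjugating enzymes, secreted proteins, acute-phase proteins, and coagulation and complement genes. None of these 4 passed with an estimated correlation in that fit (adjusted p from 0.214 to 0.220). Of 14 conjugating enzymes 0 rose and 1 fell (6 fell adjusted over the list alone; 6 fell with the paired fit, and 3 under median scaling in that fit). GSTM4, a glutathione transferase gene, fell by 0.71 (SE 0.16, adjusted p = 0.0456, paired 4.71e-06). Its call was lost without DMSO array 1 (adjusted p = 0.115), 2 (0.129) or 3 (0.108) and without TCDD array 1 (0.0814), 2 (0.0618), 3 (0.130) or 4 (0.102). Its other probe gave -0.06, and median scaling gave -0.41. SULT2A1, a steroid sulfotransferase gene, fell by 1.95 with the paired fit (SE 0.27, adjusted p = 9.62e-05, unpaired 0.172). GSTA1 and GSTA2 both fell by 1.18 with the paired fit, but they are near-identical copies that probes may not separate. The list was lower than other genes (median -0.33, camera adjusted p = 0.00232, and adjusted p = 0.773 with an estimated correlation). Pairing gave it adjusted p = 1.26e-04 and adjusted p = 0.214 with an estimated correlation.

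Of 14 hepatocyte secreted proteins 0 rose and 0 fell (4 fell adjusted over the list alone), and 7 fell with the paired fit, or 1 under median scaling. TF (transferrin) fell by 0.77 (paired SE 0.093, adjusted p = 1.96e-05), VTN (vitronectin) by 0.69 and APOA1 (an apolipoprotein of HDL) by 0.76, with unpaired adjusted p of 0.168, 0.125 and 0.161. With median scaling in the paired fit they gave -0.48, -0.40 and -0.48 and none of these 3 was called. The list was lower than other genes (median -0.35, camera adjusted p = 0.0153, and adjusted p = 0.773 with an estimated correlation). That call was lost without DMSO array 2 (adjusted p = 0.12), DMSO array 3 (0.0827) or TCDD array 4 (0.194), and without the filter on dim probes (0.165). Pairing gave it adjusted p = 2.76e-05 and adjusted p = 0.220 with an estimated correlation.

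Of 18 acute-phase proteins 0 rose and 0 fell, also adjusted over the list alone, and the list did not pass (median -0.38, camera adjusted p = 0.132). With the paired fit 1 rose and 9 fell (1 and 3 under median scaling), and the list passed (camera adjusted p = 1.22e-05, and adjusted p = 0.214 with an estimated correlation). The 3 fibrinogen genes FGA, FGG and FGB fell by 0.99 (paired SE 0.068, adjusted p = 4.93e-08), 1.0 (adjusted p = 1.14e-07) and 0.91 (adjusted p = 8.27e-07) in 4 of 4 pairs. With median scaling they gave -0.74, -0.74 and -0.66 and were not called (paired adjusted p = 0.0789, 0.0699 and 0.121). The p-values of that fit rest on spread shared between genes, so these lost calls do not show that the 3 genes kept their level. CP (ceruloplasmin), the 1 member that rose, gave 0.43 (paired adjusted p = 0.00561) and was chosen after its value was seen. Of 9 coagulation and complement genes 0 rose and 0 fell (1 rose and 1 fell adjusted over the list alone), with 1 and 5 in the paired fit (1 and 2 under median scaling). The complement genes C5 and C6 fell by 0.88 and 1.04 and PROS1, the protein S gene, by 0.41 with the paired fit, while SERPIND1, chosen after its value was seen, rose by 0.65. The list was not called without the block (median -0.41, camera adjusted p = 0.172) and passed with it (adjusted p = 0.0137, and adjusted p = 0.220 with an estimated correlation). Its paired call was lost without the filter (adjusted p = 0.0840) and with robust eBayes without a trend (0.0650).

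These lists also differed between replicate numbers in both groups. The acute-phase median of number 4 lay 1.14 below its group mean (deviation -1.14), and those of numbers 1, 2 and 3 lay at 0.32, 0.61 and 0.03. The proliferation medians lay at -0.29, -0.48, 0.46 and 0.30 for numbers 1 to 4.

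**Figure D4:**
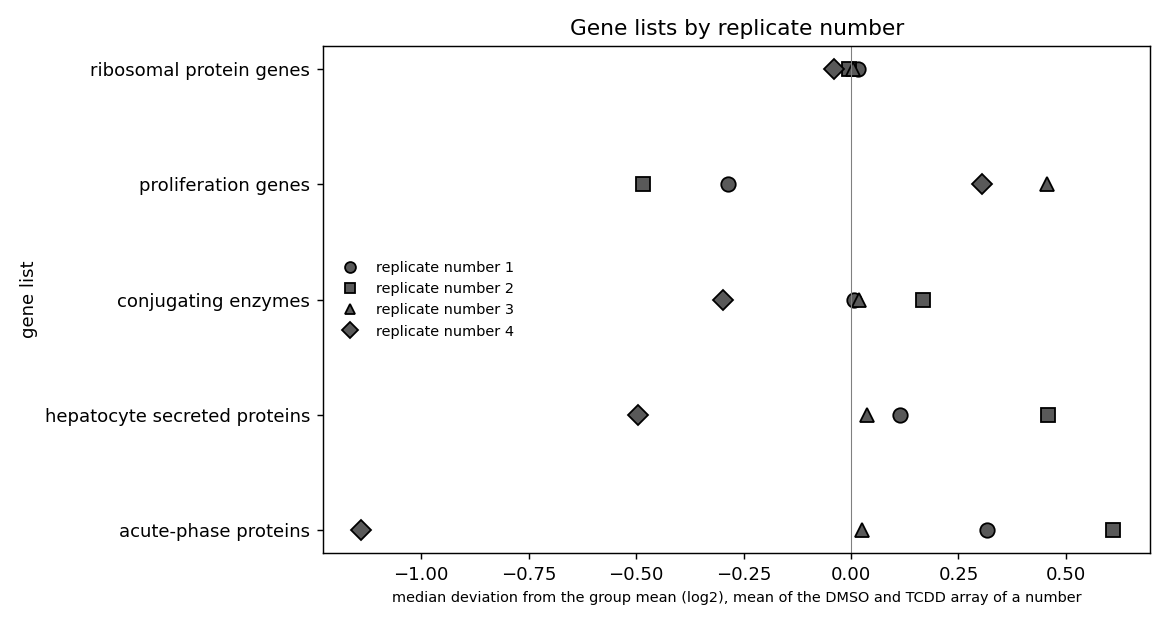
Median deviation of the members of 5 gene lists (y axis) from the mean of the array's own group (x axis, log2), averaged over the DMSO and TCDD arrays of each replicate number. Acute-phase proteins spread from -1.14 to 0.61, and ribosomal protein genes from -0.04 to 0.02.

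Of 15 cytokines and chemokines 1 rose (CCL20) and 0 fell. Adjusted over the list alone 5 rose and 1 fell, and with the paired fit 9 rose and 1 fell (10 and 0 under median scaling). CXCL8, a neutrophil chemokine, rose by 1.09 (paired SE 0.10, adjusted p = 1.51e-06, unpaired 0.199), IL1B by 1.22 (paired adjusted p = 3.94e-05, unpaired 0.122) and CCL2 by 0.67 (paired adjusted p = 3.76e-05, unpaired 0.357). IL18, the 1 member that fell, gave -0.36 (paired adjusted p = 4.98e-04) and was chosen after its value was seen. The list was higher than other genes (median 0.47, camera adjusted p = 0.0137, and adjusted p = 0.773 with an estimated correlation), but not without TCDD array 2 (adjusted p = 0.178). The paired fit gave it adjusted p = 4.34e-04 and adjusted p = 0.214 with an estimated correlation.

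Of 14 immediate early genes, which growth factors and stress switch on, 3 rose and 0 fell (5 rose and 1 fell adjusted over the list alone; 9 rose and 1 fell with the paired fit, 8 and 0 under median scaling). IER3 rose by 1.66 ± 0.21 (adjusted p = 0.00270), EGR1 by 1.08 ± 0.21 (adjusted p = 0.0251) and FOSL1 by 1.06 ± 0.23 (adjusted p = 0.0404). EGR1 was lost without DMSO array 1 (adjusted p = 0.0756), DMSO array 3 (0.0654), TCDD array 1 (0.0881) or TCDD array 3 (0.0731). FOSL1 was lost without DMSO array 1 (0.0920), 2 (0.0875) or 3 (0.108) and without TCDD array 1 (0.117), 2 (0.0649), 3 (0.108) or 4 (0.102). With the paired fit their adjusted p was 8.45e-06 and 2.38e-05, and DUSP1, chosen after its value was seen, fell by 0.37. The list was higher than other genes (median 0.38, camera adjusted p = 3.66e-04, paired 2.12e-05), with adjusted p = 0.238 with an estimated correlation and adjusted p = 0.214 with an estimated correlation in the paired fit.

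Of 19 proliferation genes 0 rose and 0 fell, also adjusted over the list alone, and with the paired fit 10 rose and 0 fell. That 10 became 6 without replicate number 3, 7 under median scaling and 4 with robust eBayes. MCM2, a replication helicase gene, rose by 0.57 (paired SE 0.097, adjusted p = 6.05e-04), and the mitotic genes CCNB1, CDK1 and AURKB rose by 0.48, 0.47 and 0.46, with unpaired adjusted p of 0.163, 0.506, 0.473 and 0.459. The list was higher than other genes (median 0.24, camera adjusted p = 0.0137, and adjusted p = 0.773 with an estimated correlation). That call was lost without DMSO array 1 (adjusted p = 0.0766), DMSO array 2 (0.396), TCDD array 3 (0.117) or TCDD array 4 (0.104). The paired fit gave it adjusted p = 7.35e-06 and adjusted p = 0.417 with an estimated correlation.

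The other 18 lists did not pass the camera test in either fit (adjusted p from 0.142 to 0.971 without the block and from 0.145 to 0.973 with it), though 2 of them passed in other settings. Bile acid genes, lower in TCDD, passed under median scaling (adjusted p = 0.00217, paired 0.00355), with the mean of a gene's probes (0.0411, paired 0.0474), without DMSO array 4 (0.0180) and without replicate number 4 in the paired fit (0.0264). Other cytochrome P450 enzymes passed under median scaling in the paired fit (adjusted p = 0.00634), with a median of 0.093 against 0.25 for all genes there. With an estimated correlation 0 lists passed in any of these paired settings. Among drug metabolism genes, 0 of 8 other cytochrome P450 enzymes were called, also adjusted over the list alone, and 1 rose and 3 fell with the paired fit, led by CYP3A5 (-1.43, paired adjusted p = 1.07e-07, unpaired 0.194). The 3 falls became 1 without replicate number 1 or 3, and 2 under median scaling. Of 12 hepatic transporters 0 were called (1 rose and 1 fell adjusted over the list alone), and with the paired fit ABCC4 rose by 0.45 and ABCA1, ABCB1 and SLC10A1 fell by 0.40, 0.43 and 0.88. SLC10A1 was above background on 3 of 4 DMSO arrays and 1 of 4 TCDD arrays, so the size of its fall leans on the background correction, and under median scaling neither ABCA1 nor ABCB1 was called. Of 9 bile acid genes 0 were called (1 rose and 3 fell adjusted over the list alone), and with the paired fit 1 rose and 4 fell, with BAAT at -0.75 and AKR1D1 at -0.34. The 4 falls became 2 without replicate number 1, 2 or 3, where SLC10A1, among the 4, had too few arrays above background to be tested. Under median scaling BAAT gave -0.50 and AKR1D1 -0.07 with no call (paired adjusted p = 0.0571 and 0.896). Of 10 hepatocyte transcription factors 0 were called (2 rose and 1 fell adjusted over the list alone), and with the paired fit 2 rose and 2 fell. FOXA1 gave -1.11 (unpaired adjusted p = 0.0552, paired 2.42e-06), while ATF5 and FOXA2 rose by 0.47 and 0.34 with the paired fit.

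Single markers of other cell types moved both ways, and camera called none of these lists. In the paired fit, however, fry called all 3 lists lower on balance. Its adjusted p was 0.00330 for biliary and progenitor, 0.0452 for mesenchymal and stellate, and 6.49e-04 for endothelial and blood cell markers. Without the block fry called only the last (adjusted p = 0.0258, against 0.229 and 0.775). Of 10 biliary and progenitor markers SOX9 fell and 0 rose (2 rose and 2 fell adjusted over the list alone). With the paired fit 3 rose and 5 fell, with KRT19 at -0.55, CD24 at -0.60 and TNFRSF12A at 0.55, and under median scaling 2 rose and 1 fell. Without replicate number 3 the paired falls were 3. Of 16 mesenchymal and stellate cell markers 0 were called (0 rose and 1 fell adjusted over the list alone), and with the paired fit LUM rose by 0.28 and COL3A1 and TWIST1 fell by 0.84 and 0.38. The paired LUM call was lost without replicate number 1 (adjusted p = 0.256) or 2 (0.116), and under median scaling COL3A1 alone of these 3 was called in the paired fit. Of 6 endothelial and blood cell markers 1 rose and 1 fell (1 rose and 2 fell adjusted over the list alone and with the paired fit). KDR, a VEGF receptor, fell by 1.17 (SE 0.14, adjusted p = 0.00234). PECAM1, an endothelial adhesion protein, rose by 1.16 ± 0.23 (adjusted p = 0.0313), with 3 of 4 DMSO arrays above background. Its call was lost without DMSO array 1 (adjusted p = 0.0572), DMSO array 3 (0.0917), TCDD array 1 (0.103), TCDD array 2 (0.0698) or TCDD array 3 (0.106).

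In metabolism, 2 of 20 fatty acid and triglyceride genes rose and 1 fell, the same numbers adjusted over the list alone (3 rose and 6 fell with the paired fit). The 6 falls became 3 without replicate number 1 or 4, 2 with robust eBayes and 1 under median scaling, where 3 rose. ANGPTL4, an inhibitor of lipoprotein lipase, rose by 1.38 ± 0.12 (adjusted p = 2.45e-04), with 0.38 and 0.44 from its other probes. CIDEC, a lipid droplet protein, fell by 1.14 (SE 0.14, adjusted p = 0.00202). GPAM, which starts triglyceride synthesis, rose by 0.75 ± 0.15 (adjusted p = 0.0313), but not without DMSO array 1 (adjusted p = 0.0858), DMSO array 2 (0.0914), TCDD array 1 (0.0989), TCDD array 3 (0.108) or TCDD array 4 (0.0768). Of 10 glucose metabolism genes 2 rose and 0 fell (3 rose and 2 fell adjusted over the list alone; 4 rose and 2 fell with the paired fit). SLC2A1, a glucose transporter, rose by 0.69 ± 0.10 (adjusted p = 0.00652) and IRS2, an insulin receptor substrate, by 0.76 ± 0.12 (adjusted p = 0.00767). PPARGC1A, a coactivator of glucose production, gave -0.98 (adjusted p = 0.0702, paired 2.55e-07). SLC2A1 was also the only call among 14 hypoxia-inducible genes (2 rose and 1 fell adjusted over the list alone; 2 rose and 3 fell with the paired fit, with 1 fall without replicate number 4 and 0 under median scaling). Of 18 cholesterol synthesis genes 0 were called, also adjusted over the list alone, and with the paired fit EBP rose by 0.25 and SC5D fell by 0.39, EBP not without replicate number 3 (adjusted p = 0.0853) or 4 (0.0916), and neither under median scaling. The cholesterol median was -0.03 while camera pointed up.

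Among stress and signalling lists, 1 of 16 endoplasmic reticulum stress genes rose and 1 fell (3 rose and 1 fell adjusted over the list alone; 3 rose and 4 fell with the paired fit, 3 and 0 under median scaling). PPP1R15A, a phosphatase subunit of the stress response, rose by 0.81 ± 0.14 (adjusted p = 0.0149, and 0.0637 without TCDD array 1). CALR, a chaperone, fell by 0.40 (SE 0.085, adjusted p = 0.0392), with -0.08 under median scaling, and its call was lost without DMSO array 1 (adjusted p = 0.0801), 2 (0.104) or 3 (0.101) and without TCDD array 1 (0.132), 3 (0.129) or 4 (0.0906). Of 17 p53 target genes 0 were called (1 rose and 1 fell adjusted over the list alone), and with the paired fit GADD45A rose by 0.64 and ZMAT3 fell by 0.43. The 2 other ZMAT3 probes gave -0.29 and -0.13, and median scaling gave -0.13 (paired adjusted p = 0.774). Of 16 interferon-stimulated genes 0 were called, also adjusted over the list alone, and with the paired fit 3 rose, with OAS3 at 0.46 and IFI44 at 0.50, and 3 fell, with IFIT1 at -0.44 (4 and 0 under median scaling). Of 13 TGF-beta and YAP target genes 0 were called, also adjusted over the list alone, and with the paired fit 4 rose, with TGFB2 at 0.74, and 2 fell, with CCN2 at -0.66. Under median scaling 2 rose and 0 fell, and without replicate number 3 the rises were 2 and without number 4 the falls were 4. Of 16 circadian clock genes 0 were called (1 fell adjusted over the list alone), and with the paired fit 3 fell, with DBP at -0.68. Without replicate number 3 none of the 15 members then measured fell in that fit (DBP adjusted p = 0.0683), and without number 1 or 2 there was 1 fall, as under median scaling. Of 7 matrix metalloproteinases and inhibitors 0 were called (1 fell adjusted over the list alone), and with the paired fit TIMP2 and MMP24 fell by 0.41 and 0.56. The other TIMP2 probe gave -0.12, and under median scaling the 2 genes gave -0.11 and -0.27 without a call (paired adjusted p = 0.810 and 0.345). The median of that list was 0.03, its mean was -0.04 and camera pointed down. Of 18 ribosomal protein genes 0 were called, also adjusted over the list alone, and with the paired fit 1 rose, RPL13 by 0.23, but not without replicate number 1 (adjusted p = 0.0911), 3 (0.138) or 4 (0.168), or under median scaling (0.110). Across the 28 lists camera called 7 without the block and 9 with it. With an estimated correlation AhR target genes alone were called without the block, and 0 lists with it.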

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

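Tests of splits and of array background were fixed before their results were seen, while the test of differences between replicate numbers and the 3 tests of the hepatocyte lists were chosen after the result was seen.

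In 128 groups of 4 values, 6 held a value far from the other 3, and chance gives about 1 in 20 groups. The median signal of DMSO array 4 was 187, against 123 to 133 on the other DMSO arrays. FGA was at 11.80 (log2) on DMSO array 4, against 13.35 to 13.48, and at 10.77 on TCDD array 4, against 12.32 to 12.57. NSG1 was at 10.26 on DMSO array 3, against 9.65 to 9.70. DLX5 was at 7.16 on DMSO array 1, against 7.67 to 7.68. PROS1 was at 13.41 on TCDD array 2, against 13.02 to 13.05. Outside the comparisons of genes, 57 called probes had no symbol in the table used here, 32 of them higher in TCDD. The largest of these changes were 5.68 ± 0.45 (adjusted p = 1.03e-04) for ILMN_2150851 and 5.58 ± 0.37 (adjusted p = 2.95e-05) for ILMN_2150856.

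Of the 35 splits of the arrays, 2 gave as many called genes as the real split, itself included (294 genes, highest other 481), so chance is not excluded for that count. The same held for genes higher (2 of 35, 135 against a highest other of 282), genes lower (2 of 35, 159 against 282) and probes (2 of 35, 426 against 707). The other split set numbers 1 and 2 against numbers 3 and 4 and parted no pair, which points to a structure of the samples by replicate number, and the remaining 33 splits called 0 genes. For genes changed at least 2-fold chance is excluded among the 35 splits (1 of 35, 99 against 88), but most of these splits leave pairs together. Among the 8 that part all 4 pairs the highest other was 0, and 8 are too few for a share under 0.05. For lists it is not (13 of 35, 7 lists against 15). Among the 8 splits that part all 4 pairs, the other 7 mix treatments between the pairs, and they called 0 genes and at most 8 lists without the block. With the replicate block the real split called 2577 genes against a highest other of 0 (1 of 8) and 9 lists against a highest other of 9 (2 of 8), and 8 splits are too few for a share under 0.05.

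Arrays of the same replicate number deviated together in both groups. Array background is argued against as the source, because among the 5448 brightest kept probes the lowest same-number correlation was 0.536 (number 1), over the limit of 0.1. The highest correlation between different numbers there was 0.497, so number 1 stood out little. Cultures of different numbers may have differed in hepatocyte and acute-phase expression: the spread of the acute-phase median over numbers (SD 0.767) lay at percentile 100 of 10000 random lists matched on level. Proliferation, cholesterol synthesis and mesenchymal genes also lay at percentile 100, the last with medians of -0.20, -0.22, 0.07 and 0.20 for numbers 1 to 4. Ribosomal protein genes lay at percentile 36.9 and p53 target genes at 11.95. The test therefore does not single out hepatocyte and acute-phase expression. The labels give no culture, day or hybridization batch, so the source of the difference stays open.

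The 4 hepatocyte lists called with the block (55 pooled members) had a median change of -0.36 in TCDD, and none of the 4 was called with an estimated correlation. Signal level is argued against as the cause, because that median lay at percentile 0 of 10000 random lists matched on level. The lists were pooled because they had been called lower, and random lists lack the correlation between their members. The percentile therefore speaks to signal level alone and does not measure chance. Under median scaling their median was -0.11, with -0.22, -0.34, -0.42 and 0.45 in pairs 1 to 4 (95% interval over the pairs -0.76 to 0.50). The median of all genes rose by 0.71 there in pair 4, which holds DMSO array 4, and by 0.04 to 0.17 in the others, and less that shift the pairs gave -0.40, -0.38, -0.53 and -0.26. Less the median of all genes, the pooled median was -0.357 with quantile normalization and -0.361 with median scaling, at percentile 0 of random lists in both. Median scaling moved 95% of genes by 0.03 to 0.32, a range too narrow to undo such a fall. The fall relative to other genes therefore did not depend on the choice between these 2 normalizations. They could hardly have differed on it, so this comparison does not settle normalization as its source. The interval under median scaling spans 0, so whether these levels fell in absolute terms cannot be told. A lower share of hepatocyte-like cells would raise the markers of other types alike. Of 26 biliary, progenitor and mesenchymal markers 7 were lower and 4 higher with the block, but under median scaling 2 were lower and 2 higher, short of the 3 each way that the test asked for in both. Fry with the block called the biliary and the mesenchymal list lower (adjusted p = 0.00330 and 0.0452), which goes against such a rise. Without the block it called neither (0.229 and 0.775), and camera called neither in either fit. A lower share therefore stays open, as do a lower expression of these genes within the cells after TCDD and a change within another cell type.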

How the results depend on the processing

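The setting that moved a count most differed between the counts, and no median of the 9 lists called in either fit changed sign. Settings that keep the block were added after seeing the data. The total of 294 genes became 489 with median scaling, 454 with array weights and 2577 with the replicate block (paired fit), and 122 to 478 with 1 array left out. Genes higher (135) became 436 with median scaling and 1165 with the block, and 72 to 202 with 1 array left out. Genes lower (159) became 53 with median scaling, 253 with array weights and 1412 with the block, and 50 to 276 with 1 array left out. The genes called with at least 2-fold change (99) became 38 with no background correction and 38 with the authors' normalized values. Background left in the signal can shrink the folds of dim probes, but this was not tested as the cause. That count of 99 became 167 with median scaling, 147 with the block and 250 at a 1.5-fold threshold, and 74 to 162 with 1 array left out. The count of probes called, total (426), became 838, 670 and 4001 with median scaling, array weights and the block, and 167 to 695 with 1 array left out. The 7 lists became 1 with an estimated correlation and 4 with fry, and 5 to 10 with 1 array left out. The paired count of 2577 became 1477 with median scaling and 1413 with robust eBayes, and 1286 to 2216 with a replicate number left out, and the 9 paired lists became 0 with an estimated correlation, 15 with fry, 11 with median scaling, 10 with the mean of a gene's probes, 8 with robust eBayes or no filter, and 9 or 10 with a number left out. The causes of these moves were not tested. Of the 294 genes, 282 were called with no background correction, 280 with the authors' values, 165 with median scaling and 293 with array weights.

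With median scaling the log2 changes of AHRR (0.0081), CRY2 (0.027), CEBPB (0.032) and POR (0.0090) reversed to above 0, as did the medians of the AhR complex (0.23), other cytochrome P450 enzymes (0.093), hepatocyte transcription factors (0.062), mesenchymal markers (0.17), endoplasmic reticulum stress (0.19), cholesterol (0.27), fatty acid (0.17), interferon (0.24) and circadian genes (0.10). Of these lists other cytochrome P450 enzymes alone passed under median scaling, and only with the block (camera adjusted p = 0.00634). Its median of 0.093 lay below the 0.25 of all genes there, with 1 rise and 2 falls called. With an estimated correlation 0 lists passed in that fit. The p-values of that fit rest on spread shared between genes. Its camera adjusted p for AhR target genes was 1.04e-74, so its list calls carry the same limit. Under median scaling the median of all genes was 0.25 higher in TCDD. That shift was unequal, 0.71 in pair 4, which holds DMSO array 4, and 0.04 to 0.17 in the other pairs. The stricter filter reversed the AhR complex (0.027) and metalloproteinases (-0.069), array weights reversed mesenchymal (0.024) and cholesterol genes (0.0066), and no filter reversed glucose genes (-0.032) and metalloproteinases (-0.018). With 1 array left out the medians ran from -0.15 to 0.027 (AhR complex), -0.35 to 0.054 (other cytochrome P450), -0.29 to 0.046 (biliary), -0.18 to 0.052 (mesenchymal), -0.0026 to 0.10 (p53), -0.071 to 0.022 (cholesterol), -0.011 to 0.20 (glucose), -0.088 to 0.030 (interferon), -0.23 to 0.13 (metalloproteinases) and -7.4e-04 to 0.043 (ribosomal).

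The block changed no call to uncalled among the named genes, and 76 named genes and 2 lists gained a call with it. Up to 4 members per list were named for their small adjusted p in that fit, so the number of genes gained follows in part from how they were chosen. Without the block acute-phase proteins gained a call with median scaling (adjusted p = 8.40e-05), array weights (0.0226) and the mean of a gene's probes (0.0411), and without DMSO array 4 (4.00e-04) or TCDD array 2 (0.0213). Coagulation and complement genes gained one with median scaling (0.0199) and the stricter filter (0.0235), and without DMSO array 4 (0.0264). No slide was named, so the slide block was not run. SHISA2 had no value with a replicate number left out, CYP1A1 none without number 2, RSPO1 none without number 4, and SLC10A1 and CYP2C8 none without number 1, 2 or 3, because too few arrays were above background. Signal over background limits the folds of genes near background in 1 group, such as CYP1A1. CYP1A2 was tested with no filter alone (adjusted p = 0.0175, paired 0.00238), and no size is given because its DMSO signal was background.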

Other observations

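The 3 tests on added gene lists were written before their results were seen, on lists written after the values of all genes were seen and without the genes that prompted them. Some genes of Wnt signalling, cell junctions and amino acid transport moved beside those of the fixed lists. DKK1, an inhibitor of Wnt signalling, fell by 1.14 (SE 0.22, adjusted p = 0.0281), WNT5A, a Wnt ligand, fell by 1.06 (SE 0.20, adjusted p = 0.0201), and CDH1 (E-cadherin) fell by 1.08 (SE 0.16, adjusted p = 0.00617). SLC3A1, a subunit of an amino acid carrier, rose by 1.41 ± 0.17 (adjusted p = 0.00203). These 4 genes were chosen after their values were seen.

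The hypothesis that other Wnt pathway genes changed too, beside NKD2, RSPO1, DKK1 and WNT5A, was tested on 29 measured genes. Of these 0 rose and 3 fell without the block, and 2 rose and 6 fell with it. A one-sided rank test of the absolute moderated t of the paired fit (change over its error) gave an adjusted p of 0.466 over the 3 lists. For cell junction genes beside CDH1, CGN and PPL, 27 measured genes held 0 calls without the block, and 2 rises and 4 falls with it (camera with the block, adjusted p = 0.466). For amino acid transporters beside SLC7A5, SLC7A11 and SLC3A1, 21 measured genes held 0 calls without the block, and 4 rises and 2 falls with it (camera with the block, adjusted p = 0.466). None of the 3 tests passed, which does not show that the other members did not change.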
